A study of Mus musculus with 52 samples.

How the data were processed

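The expression of genes in CD103-positive conventional type 1 dendritic cells (cDC1) of mouse bone marrow cultures was measured by sequencing the 3' ends of polyadenylated RNA in bulk, with barcoded primers carrying unique molecular identifiers (UMIs). Per the labels' protocols, the libraries were run on a NextSeq 500, and the authors made tables of UMI counts per gene with the Drop-seq pipeline, reads being annotated on the GRCm38 genome with Ensembl release 75. The submitters' processing notes also name DESeq2 1.14.1 and the build GRCm38.p6. The aligner, its version and whether counting used the strand are not given in the sources used here, so reads of overlapping and antisense genes could not be told apart. The deposited table holds whole-number UMI counts, 1 column per library, and no normalised values. Paralogs whose reads the counting could have split, such as Ifitm1, Ifitm2 and Ifitm3, Bcl2a1b and Bcl2a1d, Ifit3 and Ifit3b, Hspa1a and Hspa1b, Ifnl2 and Ifnl3 and the H2 genes, carry that uncertainty.

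The table had 23136 lines, of which 1 held a text entry in place of a count and was left out. Gene symbols that a spreadsheet had turned into dates stood in 20 lines with 0.105% of the counts, and these were named in no result. At least 1 count was present for 20995 genes. The libraries held between 42666 and 438491 counts with a median of 295484.5, and the lowest totals after the smallest were 54107, 110698 and 174587. A count of 0 in a library allows up to 3 counts, which was 10.2 CPM at the median depth. This limit covers counting error only. The sources do not say that the 4 libraries of a group came from separate animals or cultures, so that p-values measure the spread between these samples, which may be technical. Replicate pairs within a group differed by more than counting noise, with chi-square per degree of freedom between 1.41 and 3.35 over 78 pairs, and no library was found to be present more than once.

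Counts were analysed in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (TMM scaling, filterByExpr by group, robust dispersion) and Benjamini-Hochberg adjustment over all genes tested, with an adjusted p of at most 0.05 as the threshold. An adjusted p of a single gene comes from that test unless another setting is named beside it. The 36 libraries at 4 h were fitted together (5754 genes, 9 groups), as were the 16 at 24 h (5273 genes, 4 groups) and, for the difference between the times, the untreated and PGE2 groups of both times (5403 genes). Fold changes are on the log2 scale with the standard error (SE) of the fit. Levels are mean CPM (counts relative to the library total as adjusted by TMM scaling) with the SD over 4 libraries. The labels' own threshold for a changed gene, a log2 fold change of 1.5 together with an adjusted p of 0.05, was applied as a second count. Where every library of a group was at 0, the fold was computed against 3 counts over the whole group and is a lower bound. Where a group held 1 to 3 counts, CPM values are given without a fold.

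The lists of genes were fixed before the data were examined. They cover cDC1 identity (22 genes), MHC class I (16) and class II presentation (12), maturation and costimulation (18), interferon-stimulated genes (34), effector cytokines and chemokines (21), cAMP and CREB targets (23), the prostaglandin pathway (18), TLR3 signalling (14), NF-kB targets (20), glycolysis and hypoxia (21), cholesterol synthesis (19), proliferation (22), apoptosis (17), heat shock, ER and integrated stress (16) and transcripts encoded by mitochondria (13). Markers of other cells covered cDC2 (12), macrophages and monocytes (16), plasmacytoid dendritic cells (12), granulocytes and mast cells (14), lymphocytes (12) and melanoma (10). Members called are given over all genes tested and also adjusted over the list alone. Each list with at least 2 tested members was tested with fry of limma 3.58.1 on log2 CPM with voom weights, adjusted over the lists of 1 comparison. This tests whether the genes of a list move on balance one way and does not compare them with other genes. The same lists were tested with camera at an estimated correlation between genes.

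A PGE2 score was computed per library at 4 h as the mean log2 CPM (prior count 2) of the genes called higher in control conditioned medium (CM) than in PGE2-deficient CM minus that of the genes called lower. It was scaled so that untreated cells averaged 0% and PGE2-treated cells 100%. The signature comes from other libraries than those tested with the score. Scores were compared with two-sided exact permutation tests between groups of 4, whose smallest possible p is 0.0286, adjusted over 14 tests. Overlaps of called genes were tested with Fisher's exact test against independent lists, and fold changes were correlated across genes, which are not independent replicates. All pairs of comparisons set side by side in this way used different libraries.

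The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 8 largest positive and the 8 largest negative log2 fold changes among called genes with at least 20 CPM in the higher group and no overlap between the libraries, leaving out predicted and ribosomal protein genes. It added up to 4 members of each list with the smallest adjusted p, and always Irf8, Batf3, Xcr1, Clec9a, Tlr3, Ptger2, Ptger4, Ccr7, Crem, Il12b, Cxcl9, Cxcl10 and Ifnb1. Genes outside it are marked as chosen after their values were seen. Not every gene it allows is printed, and list members whose calls ended without single libraries were mostly left unnamed after that was seen. The score test of the EP4 against the EP2 antagonist and 2 exclusions of libraries, each of a pair, were chosen after seeing the data. The alternatives were DESeq2 1.42.0, DESeq2 size factors or library totals in edgeR, no expression filter, only the groups compared, the replicate letter as a block, each library left out in turn, camera for the lists, and other signatures, prior counts and scalings for the score. Gene positions come from the GENCODE M21 annotation of GRCm38.

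The main test was run on simulated counts with the genes' overall shares and the library sizes of the data and a biological coefficient of variation of 0.15. For PGE2 at 4 h, 51 of 95 genes changed 2-fold (53.7%) and 88 of 98 changed 4-fold (89.8%) were called, with 4 false calls among 5523 genes. For PGE2 at 24 h, 52 of 93 (55.9%) and 84 of 92 (91.3%) were called, with 10 false calls among 4664 genes.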

Results

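Conventional type 1 dendritic cells (cDC1), which cross-present antigen to CD8 T cells, were analysed after exposure to prostaglandin E2 (PGE2), to medium conditioned by melanoma cells and to the TLR3 ligand poly I:C. Per the labels, the cells were grown from bone marrow of C57BL/6 mice with FLT3 ligand and GM-CSF and sorted as CD103-positive cells. There were 52 libraries in 13 groups of 4. At 4 h the 9 groups were untreated cells, PGE2, conditioned medium (CM) of BRAFV600E melanoma cells, CM of melanoma cells lacking Ptgs1 and Ptgs2 (PGE2-deficient CM), and PGE2 after an antagonist of EP1, EP2, EP3, EP4 or EP2 plus EP4. At 24 h the 4 groups were untreated cells, PGE2, poly I:C for the last 4 h, and PGE2 with poly I:C. PGE2 was given at 100 ng/ml, antagonists at 5 uM and poly I:C at 10 ug/ml. Library totals ran from 42666 (EP4 antagonist A) and 54107 counts (untreated A at 4 h) to 438491 (median 295484.5). Comparisons, lists and the naming rule were fixed in advance. The p-values measure the spread between these samples, which may be technical. The missing Ptgs genes belong to the melanoma cells, so the libraries cannot check that label. Ptgs1 in the cDC1 stood at 166 CPM (counts relative to the library total) untreated, 135 CPM in control CM and 178 CPM in PGE2-deficient CM.

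How did cDC1 respond to PGE2 within 4 h? Most tested genes of cDC1 identity fell while most tested targets of cAMP signalling rose. Batf3, a factor needed for cDC1 development (chromosome 1, 191097847 to 191108945, plus strand), fell from 231 ± 22.4 to 51.2 ± 17.4 CPM (SD, n = 4 each), a log2 fold change of -2.21 ± 0.25 (SE). Irf8, which specifies the cDC1 lineage (chromosome 8, 120736358 to 120756694, plus strand), fell from 4308 ± 446 to 2512 ± 135 CPM (-0.78 ± 0.11, adjusted p = 1.84e-09). The chemokine receptor gene Xcr1 (chromosome 9, 123852315 to 123862029, minus strand) fell from 253 ± 33.7 to 115 ± 15.7 CPM (-1.15 ± 0.26, adjusted p = 0.0013). Naaa, a lysosomal amidase gene, fell by 1.36 ± 0.15. Crem, a cAMP-induced regulator of CREB target genes (chromosome 18, 3266048 to 3337748, minus strand), rose from 6.91 ± 5.61 to 172 ± 38.0 CPM (4.89 ± 0.65, adjusted p = 1.62e-06).

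Among the largest increases, Sdcbp2 stood at 68.3 ± 12.2 CPM with PGE2 and had no count in untreated cells, which is at least 24.3-fold. Rgs9, a regulator of G protein signalling, stood at 20.6 ± 14.9 CPM against no count, at least 7.33-fold. Ctla2a, a protease inhibitor gene, rose by 5.05 ± 0.66 and Clec7a, which encodes the beta-glucan receptor dectin-1, by 4.76 ± 0.69. Cd93, Clec4n and the endocytic adaptor gene Dab2 stood at 51.3, 48.3 and 59.0 CPM with PGE2 against 0.747, 0.862 and 1.43 CPM. Cd180, a TLR4-related surface receptor, fell by 3.33 ± 0.56, Sema4d by 2.91 ± 0.57 and the proton channel gene Hvcn1 by 2.87 ± 0.48. Chosen after their values were seen, the interferon-induced membrane protein genes Ifitm1, Ifitm2 and Ifitm3, which can share reads, rose by 1.66 ± 0.12, 1.93 ± 0.15 and 2.01 ± 0.22. Ifitm1 had the smallest adjusted p of all genes (3.15e-28, 5443 ± 120 against 1724 ± 192 CPM). Under the test 493 of 5754 genes were called, 300 higher and 193 lower, of which 156 changed by at least 1.5 on the log2 scale. With library totals alone the split was 237 higher and 332 lower, and the median of all genes was -0.13.

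By group of genes, the cDC1 identity list had 1 of 20 tested members higher and 12 lower (1 and 14 adjusted over the list alone, fry adjusted p = 3.32e-06). The exception was Plet1, which rose by 2.42 ± 0.25 to 5456 ± 238 CPM. Of 10 cAMP and CREB targets 7 rose and none fell (9 and 1 adjusted over the list alone, adjusted p = 9.82e-07), among them the phosphodiesterase gene Pde4b (2.82 ± 0.32) and Nfil3 (3.31 ± 0.51), while Nr4a2 stood at 56.4 against 2.17 CPM. In the maturation list 4 of 9 rose (5 adjusted over the list alone, adjusted p = 6.97e-06), namely Cd83 (1.94 ± 0.24), Marcks (1.31 ± 0.24), Relb (1.55 ± 0.34) and Socs2 (2.52 ± 0.60). NF-kB targets had 6 of 13 higher (8 adjusted over the list alone, adjusted p = 5.26e-06), with Il1b at 2.84 ± 0.38, Nfkbie at 2.13 ± 0.34, Tnfaip2 at 0.99 ± 0.17 and Nfkbia, which encodes an NF-kB inhibitor, at 0.84 ± 0.17. Of 13 apoptosis genes 4 rose (5 adjusted over the list alone, adjusted p = 0.000109), such as the survival genes Bcl2a1d (1.98 ± 0.40), Bcl2a1b (1.84 ± 0.44) and Mcl1 (0.68 ± 0.16).

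Of these further lists 4 passed with at most 3 called genes each, and class II genes went both ways without passing. Of 12 effector cytokine genes 3 rose (3 adjusted over the list alone), such as the chemokine genes Ccl17 (1.26 ± 0.15) and Cxcl16 (1.06 ± 0.16), with adjusted p = 0.00765 and adjusted p = 0.109 with an estimated correlation. In the prostaglandin list 2 of 7 fell (2 adjusted over the list alone), the prostaglandin D synthase gene Hpgds (-1.63 ± 0.27) and Ptger3, which encodes EP3 (-1.47 ± 0.37), with adjusted p = 0.000682 and adjusted p = 0.0544 with an estimated correlation. Of 4 tested macrophage genes 2 fell (2 adjusted over the list alone, adjusted p = 0.000523), such as Ccr2 (-1.49 ± 0.38). Of 15 MHC class I genes 1 fell, 0 adjusted over the list alone, with adjusted p = 0.0282 and adjusted p = 0.303 with an estimated correlation. Of 12 class II genes 4 rose and 2 fell (5 and 2 adjusted over the list alone, adjusted p = 0.62), among them Ctss (0.48 ± 0.12) and H2-DMb1 (-0.59 ± 0.12). Its median was -0.11 and its mean -0.04, while the test pointed up.

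The other lists did not pass for PGE2 at 4 h either. Of 12 interferon-stimulated genes 1 fell (1 adjusted over the list alone, adjusted p = 0.69). Of 14 cholesterol genes 2 fell, such as Fdps (-1.64 ± 0.33) (2 adjusted over the list alone, adjusted p = 0.66), with a median of 0.25 and a mean of -0.03 while the test pointed down. Of 12 glycolysis genes 2 rose (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.0645). Of 12 stress genes Xbp1 rose (0.54 ± 0.14, adjusted p = 0.0699 without untreated library C) and 2 fell, such as Sdf2l1 (-0.60 ± 0.15), 1 and 2 adjusted over the list alone, with adjusted p = 0.66 and a median of 0.21 while the test pointed down. No member was called, or called adjusted over the list alone, among 9 TLR3 genes (Rela 0.49, list adjusted p = 0.225), 21 proliferation genes (Top2a -0.13, list adjusted p = 0.322) and 6 mitochondrial transcripts (mt-Cytb 0.18, list adjusted p = 0.167).

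Did PGE2 change its own receptors and the genes of T cell recruitment at 4 h? Ptger2, which encodes EP2 (chromosome 14, 44988195 to 45003820, plus strand), did not pass (0.79 ± 0.49, adjusted p = 0.406, 30.6 ± 17.6 against 21.2 ± 13.9 CPM). Ptger4, which encodes EP4 (chromosome 15, 5206661 to 5244187, minus strand), was too low to test at 6.38 ± 10.9 against 33.8 ± 22.3 CPM, as was Tlr3 at 5.80 ± 6.70 against 23.4 ± 11.2 CPM. Ifnb1 had no count at 4 h. Clec9a, a receptor for dead cells (-0.74 ± 0.40, adjusted p = 0.298), Ccr7, the receptor for lymph node homing (0.50 ± 0.26, adjusted p = 0.273), Il12b (0.27, adjusted p = 0.874), Cxcl9 (0.53, adjusted p = 0.718) and Cxcl10 (1.01, adjusted p = 0.302) were not called.

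Few of the markers of other cells that the count table held were tested. None of 8 granulocyte and mast cell markers and none of 9 lymphocyte markers passed the expression filter at either time, and 6 and 3 more had no entry and cannot be judged. Of 12 cDC2 markers only Cd209a was tested at 4 h (29.3 ± 22.5 CPM untreated), joined at 24 h by Cd7 (4.42 CPM untreated). Tcf4 was the only tested marker of plasmacytoid dendritic cells, at 24 h alone, with 24.1 ± 7.19 CPM untreated at 4 h. Kit was the only tested melanoma marker of 6 in the table, at 17.2 ± 17.3 CPM in untreated cells at 4 h and 17.2 CPM at 24 h. Lyz2 (807 ± 222 CPM), Csf1r (214 CPM), Cd68 (121 CPM) and Ccr2 (71.4 CPM) were the tested macrophage genes.

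How much of the response to tumour medium depended on the melanoma cells' Ptgs genes? Control CM against PGE2-deficient CM changed many of the genes that PGE2 changed. Crem stood at 167 ± 44.9 CPM in control CM and 36 ± 44.7 CPM in PGE2-deficient CM (2.18 ± 0.43, adjusted p = 0.0016, n = 4 each), where library B held 100.7 CPM and the others between 3.91 and 30.4 CPM. With only the groups compared Crem was not called (adjusted p = 0.169, and called under the other alternatives). Batf3 fell from 172 ± 49.0 to 76.7 ± 24.6 CPM (-1.14 ± 0.23, adjusted p = 0.0002). Cd83, a marker of maturing dendritic cells, rose from 110 ± 42.4 to 342 ± 29.6 CPM (1.65 ± 0.20, adjusted p = 6.05e-10), and Ccl17 from 671 ± 117 to 1389 ± 242 CPM (1.08 ± 0.13, adjusted p = 4.21e-10).

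Further increases were Rgs9 (3.25 ± 0.73), Sdcbp2 (2.41 ± 0.45), Ctla2a (2.40 ± 0.44), Sema7a (2.35 ± 0.54), Dab2 (2.34 ± 0.41) and the actin-severing protein gene Scin (2.13 ± 0.36). Ctla2a and Scin were not called with only the groups compared (adjusted p = 0.107 and 0.0849) and were under the other alternatives. PGE2-deficient CM library B held most counts of Rgs9, Sdcbp2 and Ctla2a in that group (means of 3.15, 11.0 and 28.7 CPM, the last with a standard deviation of 39.6), and without it Ctla2a stood at 4.07, Crem at 3.49, Dab2 at 2.96 and Scin at 2.87, with Rgs9 and Sdcbp2 left at 0 and 1 counts. Further decreases were Cd180 (-3.06 ± 0.68), Cited2 (-2.26 ± 0.42) and Sdc3 (-1.70 ± 0.31). Irf8 was lower by 0.46 ± 0.11 (adjusted p = 0.00168, 3269 ± 199 against 4583 ± 662 CPM). Without PGE2-deficient CM library C it was lower by 0.37 with adjusted p = 0.0518. Xcr1 was lower by 0.80 ± 0.23 (adjusted p = 0.0274, 176 ± 33.8 against 312 ± 96.9 CPM), and its adjusted p rose to 0.105, 0.0863 or 0.126 without control CM library B, C or D and to 0.132 or 0.131 without PGE2-deficient CM library A or C, to 0.108 with DESeq2 and to 0.0627 without the shallow EP4 antagonist A and untreated A. Clec9a (-0.65, adjusted p = 0.591), Ptger2 (0.90, adjusted p = 0.281), Ccr7 (0.45, adjusted p = 0.421), Il12b (0.25), Cxcl9 (-0.01) and Cxcl10 (-0.07) were not called. Of 5754 genes 227 were called, 140 higher and 87 lower, 52 of them by at least 1.5. Library totals alone gave 120 and 121, and the count fell to 141 without PGE2-deficient CM library A.

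In control CM the cDC1 identity list had 1 member higher, Plet1 (1.69 ± 0.23, adjusted p = 0.0571 with only the groups compared), and 7 of 20 lower, including Naaa (-0.86 ± 0.14) and Ppt1 (-1.33 ± 0.23), against PGE2-deficient CM (1 and 9 adjusted over the list alone, adjusted p = 0.00164). Of 10 cAMP and CREB targets 6 rose, such as Pde4b (1.67 ± 0.29), Pde3b (1.89 ± 0.40) and Nr4a2 (2.32 ± 0.50), and Rgs2 fell (-1.15 ± 0.25), 7 and 1 adjusted over the list alone (adjusted p = 5.93e-05). Of 9 maturation genes 2 rose, such as Cd83 (5 adjusted over the list alone, adjusted p = 6.35e-05). Traf1 (1.67 ± 0.28), Il1b (1.80 ± 0.33) and Tnfaip2 (0.92 ± 0.16) were the 3 of 13 NF-kB targets that rose (5 adjusted over the list alone, adjusted p = 0.000783). Of 13 apoptosis genes 2 rose (3 adjusted over the list alone, adjusted p = 0.00164). Ccl17 and Cxcl16 (0.84 ± 0.14) were the 2 of 12 effector genes that rose (2 adjusted over the list alone), with adjusted p = 0.0449 and adjusted p = 0.153 with an estimated correlation. Hpgds alone fell in the prostaglandin list (-1.40 ± 0.26, 2 of 7 adjusted over the list alone), with adjusted p = 0.0139 and adjusted p = 0.102 with an estimated correlation. Among 4 macrophage genes 1 fell (1 adjusted over the list alone), with adjusted p = 0.00537 and adjusted p = 0.056 with an estimated correlation.

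Lists that did not pass in this comparison held few called genes. Among 14 cholesterol genes 2 fell, such as Fdps (-1.23 ± 0.31) (1 higher and 2 lower adjusted over the list alone, adjusted p = 0.953), whose median of 0.14 and mean of 0.02 opposed the sign of the test. Among 12 stress genes 2 fell (2 adjusted over the list alone, adjusted p = 0.0689). Among 12 class II genes 1 fell (1 higher and 1 lower adjusted over the list alone, adjusted p = 0.975). No member was called, or called adjusted over the list alone, for MHC class I (adjusted p = 0.131), interferon-stimulated genes (0.841, median 0.01, mean -0.11), TLR3 signalling (0.975, median -0.10, test up), glycolysis (0.904, median 0.03, mean -0.05), proliferation (0.67) and mitochondrial transcripts (0.16).

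The genes called for PGE2 and for CM overlapped. Of the 140 genes higher in control CM than in PGE2-deficient CM, 117 were also higher with PGE2 (83.6%, 7.30 expected, Fisher's exact p = 6.2e-136). Of the 87 lower, 63 were also lower (72.4%, 2.92 expected, Fisher's exact p = 1.96e-77), and none was opposite. Across all genes the fold changes correlated at r = 0.571 (rho = 0.424), genes not being independent replicates.

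**Figure D1:**
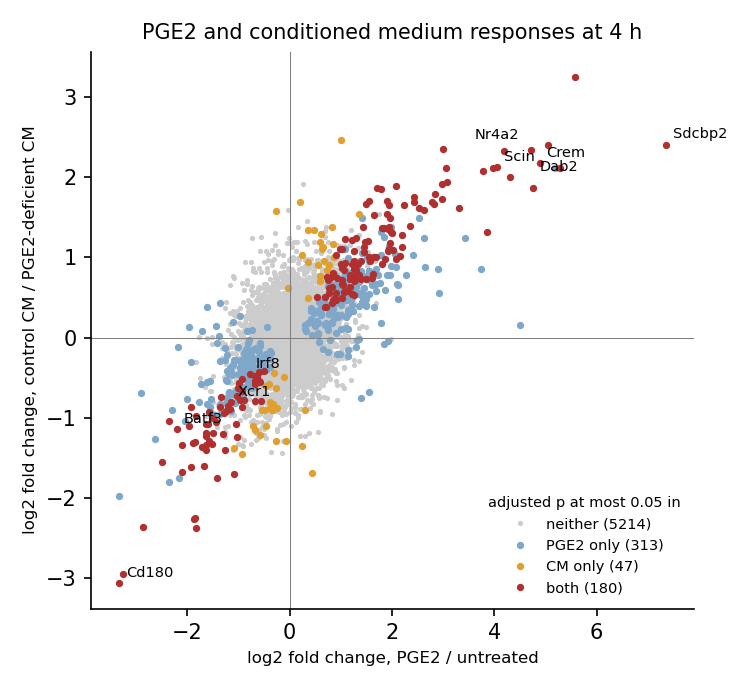
Each point is 1 of 5754 genes at 4 h, with the log2 fold change of PGE2 over untreated cells on the x axis and that of control CM over PGE2-deficient CM on the y axis, coloured by calls (adjusted p of at most 0.05). Of the genes called in both, 117 lay in the upper right, such as Crem and Sdcbp2, and 63 in the lower left, such as Batf3 and Cd180.

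Against untreated cells, control CM changed 435 genes (277 higher, 158 lower, 127 by at least 1.5, and 228 and 240 with library totals, where the median of all genes was -0.10). Crem (4.80 ± 0.65), Ctla2a (4.95 ± 0.66), Clec7a (4.45 ± 0.71) and Ccl17 (1.81 ± 0.14) rose, and Sdcbp2 was at least 21.5-fold and Rgs9 at least 12-fold higher. Cd180 (-4.20 ± 0.61), Hvcn1 (-2.71 ± 0.45), Cited2 (-2.31 ± 0.43), the lipase gene Lipa (-2.23 ± 0.34), Batf3 (-1.60 ± 0.23) and Irf8 (-0.41 ± 0.11, adjusted p = 0.0702 with no filter) fell. The cDC1 list had 1 higher and 9 lower of 20 (1 and 12 adjusted over the list alone, adjusted p = 0.000356), and cAMP targets had 7 higher and 1 lower of 10 (9 and 1 adjusted over the list alone, adjusted p = 5.22e-06). PGE2-deficient CM against untreated cells changed only 5 genes. The interferon-induced genes Ifitm2 (0.83 ± 0.15, adjusted p = 0.00242) and Ifitm1 (0.56 ± 0.11, adjusted p = 0.00496), the chemokine gene Ccl17 (0.72 ± 0.15, adjusted p = 0.00496) and the actin crosslinker gene Actn1 (0.89 ± 0.21, adjusted p = 0.0376) rose, and Gm26917 fell (-0.63 ± 0.15, adjusted p = 0.0347). Gm26917 and Actn1 lay outside the rule and were chosen after their values were seen. The count was 2 without untreated library B and 0 without untreated library D or PGE2-deficient CM library B. Without the last, adjusted p was 0.423 for Ifitm2, 0.568 for Ifitm1 and 0.195 for Ccl17, and without untreated library D it was 0.0627, 0.0627 and 0.195. Ifitm1 had adjusted p = 0.131 without untreated library B and 0.0569 with only the groups compared, and both Ifitm1 and Ccl17 had 0.0699 with DESeq2. All list tests of that comparison had adjusted p of at least 0.181.

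**Figure D2:**
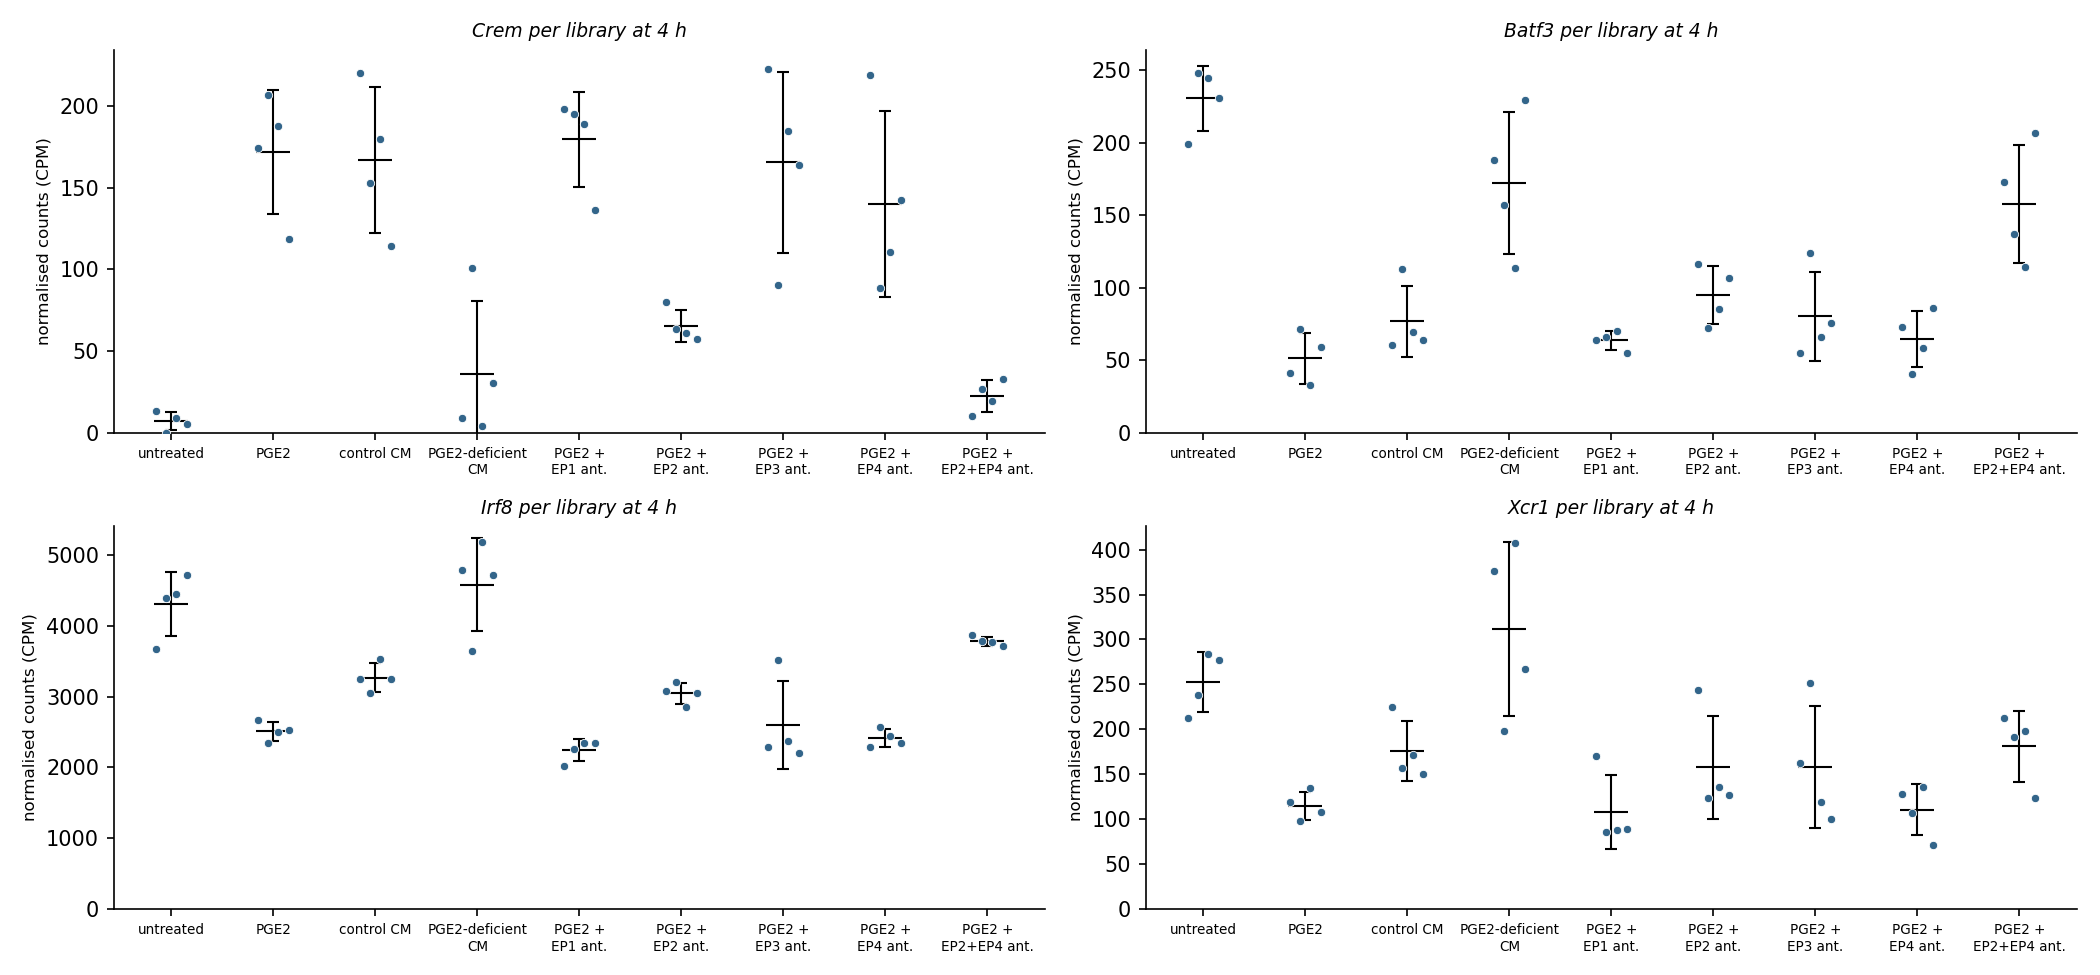
CPM per library (y axis) of Crem, Batf3, Irf8 and Xcr1 in the 9 groups at 4 h (x axis), with points for libraries and lines for the mean ± SD of 4. Crem averaged 172 CPM with PGE2 and 22.3 CPM with the antagonists of EP2 plus EP4, where Irf8 stood at 3783 ± 64.7 CPM.

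Which receptors carried the response to PGE2? A score of the CM signature (140 genes up minus 87 down), formed from other libraries, was compared between untreated cells (0 ± 7.29%) and PGE2 (100 ± 3.34%). The score stood at 69.2 ± 3.78% with the EP2 antagonist, 88.9 ± 0.939% with the EP4 antagonist and 18.2 ± 3.99% with the combined antagonists (mean ± SD, n = 4). With the EP1 antagonist it stood at 100 ± 0.974% and with the EP3 antagonist at 86.1 ± 24.1%, where library B was at 49.9% and the others between 97.0 and 99.5%. Differences from PGE2 on the log2 scale were -0.75 for EP2, -0.27 for EP4 and -2.00 for the combination (exact permutation p = 0.0286 each, adjusted p = 0.0333), against 0.00 for EP1 (exact permutation p = 0.971) and -0.34 for EP3 (exact permutation p = 0.257, adjusted p = 0.277). The EP4 difference depended on the choice of signature, being -0.06 (adjusted p = 0.523) with signature genes from 24 h of PGE2, and it had adjusted p between 0.0286 and 0.523 over the alternatives. Leaving out single libraries moved EP3 between -0.45 and -0.04, and EP1 changed sign without PGE2 library A (-0.03), PGE2 library D (-0.005) or EP1 antagonist library A (-0.01). The combination differed by -1.246 from EP2 alone and by -1.73 from EP4 alone, and stayed above untreated cells by 0.44 (adjusted p = 0.0333 each). The last had adjusted p = 0.0667 without any one of the 4 combined libraries and was 0.18 (adjusted p = 0.0727) with signature genes from 24 h of PGE2 and 0.54 (adjusted p = 0.0667) with genes changed by at least 1. The EP4 antagonist scored above the EP2 antagonist by 0.48 (adjusted p = 0.0333), a test chosen after seeing the data. The falls of EP2 and EP4 alone sum to 1.03 and that of both was 2.00, an excess of 0.97 (SE 0.08).

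**Figure D3:**
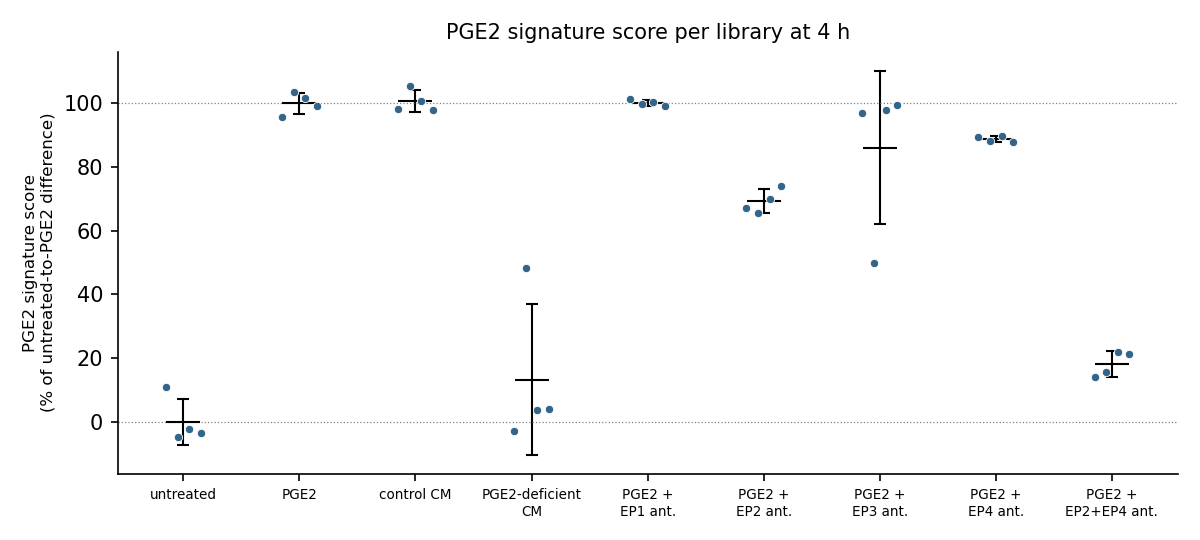
PGE2 score in % of the PGE2 response (y axis) for the 9 groups at 4 h (x axis), with points for libraries and lines for the mean ± SD of 4. Untreated cells averaged 0%, PGE2 100%, and the combined antagonists 18.2%, and 1 library each of PGE2-deficient CM (48.3%) and of the EP3 antagonist (49.9%) lay apart. The CM groups define the signature, so that their scores are not independent of it.

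The labels of the combined group conflict. Its titles name antagonists of EP2 and EP4. Its treatment entry names SC-19220 (elsewhere the EP1 compound) and L161,982 (the EP4 compound). Its titles are followed here.

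With the EP2 antagonist the receptor-associated gene Ramp3 fell from 366 ± 30.2 to 75.8 ± 10.5 CPM (-2.31 ± 0.41, adjusted p = 0.00652) and Il1b from 121 ± 27.0 to 28.7 ± 8.86 CPM (-2.12 ± 0.32, adjusted p = 3.92e-06). Sdcbp2 (-2.06 ± 0.42), Pde4b (-1.08 ± 0.24) and Bcl2a1b (-1.63 ± 0.41) also fell, and Map1b stood at 0.622 against 29.6 CPM. In all, 24 of 5754 genes were called, 5 higher and 19 lower (7 by at least 1.5, and 6 and 12 with library totals). The count was 9, 7 or 15 without PGE2 library A, B or C and 15, 13 or 7 without EP2 antagonist library A, B or D. It was 82 with only the groups compared and 43 without PGE2-deficient CM library B and EP3 antagonist library B, an exclusion chosen after seeing the data. Of 10 cAMP targets 1 fell (5 adjusted over the list alone, adjusted p = 0.00208), of 13 NF-kB targets 1 fell (6 adjusted over the list alone, adjusted p = 0.00208), and of 9 maturation genes none was called (5 lower adjusted over the list alone, adjusted p = 0.00622). Batf3 stood at 95.1 ± 20.2 CPM, Irf8 at 3048 ± 150 CPM and Crem at 65.4 ± 10.0 CPM (adjusted p = 0.105, but called with no filter, with only the groups compared and without that pair).

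The other single antagonists changed few genes. With the EP3 antagonist Dst (-1.36 ± 0.30), Btg1 (-1.30 ± 0.29) and Ccdc88a (-1.03 ± 0.24) fell and Rpl18 rose (0.73 ± 0.16), the last outside the rule and chosen after its value was seen. Dst, Btg1 and Ccdc88a lost their calls with DESeq2 (adjusted p = 0.0827 each), with no filter and when most single libraries were left out (adjusted p up to 0.227, 0.228 and 0.295). Library totals gave 3 higher and 3 lower, and the count was 0 or 1 without PGE2 library A or B and 0, 1, 0 or 1 without EP3 antagonist library A, B, C or D. With the EP4 antagonist Btg1 fell (-1.58 ± 0.34) and the phosphatase regulator gene Arpp19 rose (0.80 ± 0.17), both with adjusted p = 0.0252, which rose to 0.0887 with DESeq2, to 0.0894 and 0.169 with no filter and to at most 0.218 and 0.242 without single libraries. The count was 0 without PGE2 library A or B, 1 without PGE2 library D, 1 without EP4 antagonist library A and 0 without its library B, C or D. Under the EP1 antagonist edgeR called 0 genes, with 276 at unadjusted p under 0.05, and DESeq2 called 0. All lists had adjusted p of at least 0.493 for EP1, 0.188 for EP3 and 0.0761 for EP4. At 4 h, Batf3 stood at 63.7, 80.2 and 64.5 CPM with the EP1, EP3 and EP4 antagonists and Crem at 180, 166 and 140 CPM.

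The combined antagonists reversed much of the PGE2 response. Against PGE2 alone, Crem fell from 172 ± 38.0 to 22.3 ± 9.59 CPM (-3.02 ± 0.45), Batf3 rose to 158 ± 40.7 CPM (1.62 ± 0.25) and Irf8 to 3783 ± 64.7 CPM (0.53 ± 0.11, adjusted p = 6.81e-05). Xcr1 was not called (181 ± 39.6 against 115 ± 15.7 CPM, adjusted p = 0.155), but was with only the groups compared (adjusted p = 0.0429), without combined library D (0.0485) and without PGE2-deficient CM B and EP3 antagonist B (0.0465). Ramp3 (-4.18 ± 0.50), Nr4a2 (-3.63 ± 0.53), Clec7a (-3.50 ± 0.51), Il1b (-2.59 ± 0.33), Pde4b (-2.53 ± 0.28) and Cd83 (-1.60 ± 0.21) fell. Map1b was at least 15.8-fold and Rgs9 at least 11.0-fold lower. Pdgfa (2.51 ± 0.51) rose. Ccl17 was not called at 925 ± 126 against 940 ± 187 CPM. In all, 548 genes were called, 242 higher and 306 lower (110 by at least 1.5, and 384 and 259 with library totals).

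By list, the combined antagonists lowered 7 of 10 cAMP targets (7 adjusted over the list alone, adjusted p = 6.29e-07), 7 of 13 NF-kB targets (7 adjusted over the list alone, adjusted p = 2.77e-06), 4 of 9 maturation genes such as Cd83 (5 adjusted over the list alone, adjusted p = 8.68e-05) and 4 of 13 apoptosis genes (6 adjusted over the list alone, adjusted p = 7.96e-05). The cDC1 list had 7 higher, such as Batf3, Irf8, Naaa (0.80) and Ppt1 (1.34), and 2 lower, Plet1 (-2.10) and Flt3 (-0.69), of 20 (12 and 2 adjusted over the list alone), with adjusted p = 0.00183 and adjusted p = 0.0504 with an estimated correlation. Of 12 stress genes 4 rose (4 adjusted over the list alone), with adjusted p = 0.00411 and adjusted p = 0.135 with an estimated correlation, and of 7 prostaglandin genes 2 rose (2 adjusted over the list alone), with adjusted p = 0.00978 and adjusted p = 0.179 with an estimated correlation. The TLR3 list moved down without a called member (0 adjusted over the list alone), with adjusted p = 0.00411 and adjusted p = 0.246 with an estimated correlation. Of 12 effector genes 1 fell (2 adjusted over the list alone), with adjusted p = 0.0297 and adjusted p = 0.209 with an estimated correlation.

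Against the EP4 antagonist alone the combination changed 315 genes (118 higher, 197 lower, 186 and 172 with library totals), with Ramp3 (-3.85 ± 0.53) and Nr4a2 (-3.52 ± 0.55) lower and Batf3 (1.34) and Irf8 (0.57 ± 0.11) higher. The count was 205 without EP4 antagonist library C. Against the EP2 antagonist alone it changed 123 genes (34 higher, 89 lower, 51 and 74 with library totals), with Dab2 (-3.09 ± 0.45), Rhoq (-2.28 ± 0.35) and Cd83 (-1.09 ± 0.21) lower and Hvcn1 (2.49 ± 0.51) higher. The count was 72 without EP2 antagonist library D and 78 without combined library A. Against untreated cells 46 genes were called (35 higher, 11 lower, 19 and 10 with library totals). Ccl17 (1.17 ± 0.14, adjusted p = 1.93e-09), the junction gene Jup (1.94 ± 0.34, 103 ± 18.8 against 21.8 ± 18.5 CPM) and Rbx1 (0.92 ± 0.19) were higher. That count was 22, 21 or 15 without untreated library A, B or C and 27, 22 or 25 without combined library B, C or D. There the cDC1 list had 2 lower of 20 (5 adjusted over the list alone), with adjusted p = 0.0376 and adjusted p = 0.134 with an estimated correlation.

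What did PGE2 do by 24 h? Some maturation genes rose and many proliferation genes fell. Ccr7, which guides dendritic cells to lymph nodes (chromosome 11, 99144196 to 99155077, minus strand), rose from 118 ± 27.9 to 354 ± 51.4 CPM (1.64 ± 0.13, adjusted p = 2.01e-23, n = 4 each). Fscn1, an actin-bundling gene of mature dendritic cells, rose from 53.8 ± 16 to 215 ± 62.7 CPM (2.08 ± 0.19, adjusted p = 6.65e-19). Xcr1 fell from 241 ± 29.5 to 72.1 ± 14.7 CPM (-1.66 ± 0.20, adjusted p = 3.31e-12) and Irf8 from 3810 ± 81.6 to 2451 ± 107 CPM (-0.59 ± 0.08, adjusted p = 5.93e-10). Batf3 fell by 0.70 ± 0.20 (adjusted p = 0.0126, 102.2 ± 27.8 against 173 ± 48.9 CPM), with adjusted p = 0.145, 0.0572 or 0.0625 without untreated library C, PGE2 library B or PGE2 library C. Rrm2, which encodes a subunit of ribonucleotide reductase, fell from 327 ± 115 to 109 ± 37.8 CPM (-1.54 ± 0.20).

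Among the largest increases at 24 h were Cd7 (3.32 ± 0.57), Ifitm3 (3.30 ± 0.11, 1597 ± 260 against 167 ± 29.2 CPM), Tmem176b (3.21 ± 0.44), the calcium channel subunit gene Cacnb3 (3.18 ± 0.36), the GTPase gene Rac2 (3.10 ± 0.31), the lectin-like receptor gene Klrd1 (3.06 ± 0.39), Cd63 (3.03 ± 0.33) and Capg (2.88 ± 0.32). Among the largest decreases were Ccr2 (-2.95 ± 0.54), Ttc39a (-2.37 ± 0.45), Cd180 (-2.22 ± 0.44), Stfa2 (-2.16 ± 0.38), Cenph (-1.89 ± 0.50), Dtl (-1.88 ± 0.46) and Pclaf (-1.78 ± 0.26). Crem (0.98 ± 0.42, adjusted p = 0.153), Il12b (0.19, adjusted p = 0.732), Cxcl9 (-0.78, adjusted p = 0.377), Cxcl10 (-0.71, adjusted p = 0.276), Clec9a (-0.80, adjusted p = 0.2) and Ptger4 (0.02, adjusted p = 0.994) were not called. Of 5273 genes 420 were called, 250 higher and 170 lower, 91 of them by at least 1.5. Chosen after its value was seen, Ifitm1 had the smallest adjusted p (2.41 ± 0.08, adjusted p = 4.96e-68).

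At 24 h of PGE2, 8 of 17 maturation genes rose and none fell (8 adjusted over the list alone, adjusted p = 2.48e-05), among them Ccr7, Fscn1, Socs2 (2.51 ± 0.43) and Cd83 (0.88 ± 0.15). The cDC1 list had 1 higher, Plet1 (1.138 ± 0.09), and 8 of 20 lower (2 and 8 adjusted over the list alone, adjusted p = 5.36e-06), with Ppt1 at -1.77 ± 0.13 and Naaa at -1.47 ± 0.11. Of 20 proliferation genes 11 fell (1 higher and 15 lower adjusted over the list alone, adjusted p = 0.000246), such as Mcm6 (-1.62 ± 0.25), Pcna (-1.40 ± 0.28) and Top2a (-0.84 ± 0.14). Of 13 NF-kB targets 6 rose (8 and 1 lower adjusted over the list alone, adjusted p = 0.000246), such as Traf1 (1.25 ± 0.21) and Nfkbia (0.67 ± 0.13). Of 12 class II genes 5 rose (5 and 1 lower adjusted over the list alone, adjusted p = 0.00044), such as Ctss (1.144 ± 0.10) and H2-DMb2 (0.64 ± 0.17, adjusted p = 0.0574 with no filter). Of 15 apoptosis genes 4 rose (5 adjusted over the list alone), such as Mcl1 (0.51 ± 0.13, adjusted p = 0.0574 with no filter), with adjusted p = 0.000885 and adjusted p = 0.0898 with an estimated correlation. Among 9 cAMP targets 2 rose, such as Pde4b (2.33 ± 0.28), 5 adjusted over the list alone, with adjusted p = 0.00211 and adjusted p = 0.116 with an estimated correlation. Of the cDC2 markers Cd7 rose and Cd209a did not pass (1 adjusted over the list alone), with adjusted p = 0.00044 and adjusted p = 0.0522 with an estimated correlation.

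Other lists did not pass at 24 h of PGE2. H2-K1 (0.74 ± 0.12) and H2-D1 (0.41 ± 0.09) rose and Pdia3 (-0.36 ± 0.09) fell among 16 class I genes (3 and 1 adjusted over the list alone, adjusted p = 0.489), with a median of -0.05 while the mean of 0.01 and the test pointed up. Among 16 effector genes 3 rose, such as Ccl22 (1.05 ± 0.13) and Ccl5 (0.38 ± 0.07), 3 adjusted over the list alone, with adjusted p = 0.472. Ifi205 alone fell (-0.95 ± 0.23) among 31 interferon-stimulated genes (1 adjusted over the list alone, adjusted p = 0.799). Among 12 glycolysis genes 1 rose and 1 fell (1 and 1 adjusted over the list alone, adjusted p = 0.0711). Among 12 stress genes 2 fell (2 adjusted over the list alone, adjusted p = 0.886), whose median of 0.06 and mean of 0.14 opposed the test. Among 4 macrophage genes 2 rose, such as Lyz2 (0.53 ± 0.10), and Ccr2 fell (2 and 1 adjusted over the list alone, adjusted p = 0.116), with a median of 0.12, a mean of -0.54 and a test pointing up. No member was called among prostaglandin (adjusted p = 0.688), TLR3 (0.489), cholesterol (0.496) and mitochondrial genes (0.688), the last with 1 lower adjusted over the list alone.

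Tested directly, the PGE2 response differed between 24 h and 4 h for 235 of 5403 genes (114 higher, 121 lower, 95 by at least 1.5, and 176 and 90 with library totals, where the median of all genes was 0.13). Crem (-3.92 ± 0.67), Scin (-3.03 ± 0.47), Blvrb (-2.66 ± 0.32), Plet1 (-1.31), Ccl17 (-1.15) and Cd83 (-1.08) responded less at 24 h, while Tmem176b (3.64 ± 0.79), Rac2 (3.12 ± 0.40), Fscn1 (2.39), Batf3 (1.49 ± 0.32, adjusted p = 0.00065) and Ccr7 (1.12 ± 0.28, adjusted p = 0.00409) shifted upward. Irf8 (0.18, adjusted p = 0.537) and Xcr1 (-0.53, adjusted p = 0.344) did not pass. Of 21 proliferation genes 6 shifted down (9 adjusted over the list alone), such as Rrm2 (-1.64), with adjusted p = 0.00609 and adjusted p = 0.0846 with an estimated correlation. Across 4896 genes the responses at 4 and 24 h correlated at r = 0.361, with 106 genes higher at both times (12.1 expected, Fisher's exact p = 7.02e-81), 38 lower (6.21 expected, Fisher's exact p = 1.06e-20) and 6 opposite.

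How did the cDC1 respond to poly I:C? Chemokine, interferon-stimulated and maturation genes rose strongly. Cxcl10, a CXCR3 ligand gene (chromosome 5, 92346638 to 92348889, minus strand), rose from 30.7 ± 12.1 to 5338 ± 283 CPM (7.44 ± 0.14), and its neighbour Cxcl9 (92321347 to 92328079, minus strand) from 32.1 ± 30.1 to 5278 ± 155 CPM (7.42 ± 0.19). Il12b, which encodes the p40 subunit of IL-12, rose from 56.4 ± 19.3 to 3867 ± 312 CPM (6.10 ± 0.14), Ccr7 from 118 ± 27.9 to 8527 ± 541 CPM (6.19 ± 0.11) and Ccl5 from 954 ± 84.0 to 61440 ± 4040 CPM (6.02 ± 0.08, adjusted p = 9.17e-135, the smallest of all genes). Ccl4 (chromosome 11, 83662584 to 83664683, plus strand) rose from 17.7 ± 2.55 to 967 ± 210 CPM. Ifnb1, the interferon beta gene, stood at 13.3 ± 15.4 CPM with poly I:C and had no count in the other 3 groups, including PGE2 with poly I:C.

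Among the largest increases were Rsad2 (8.18 ± 0.21, 1847 ± 272 against 5.95 ± 0.509 CPM), Ifit1 (7.90 ± 0.20), Ifnl2 (156 ± 88.9 CPM against no count, at least 70.5-fold), Nipal1 (at least 53.5-fold), Ifnl3 (at least 53.1-fold), Nectin2 (at least 50.1-fold) and the death receptor gene Fas (at least 47.9-fold), and Cxcl11 stood at 402 ± 14.3 against 0.688 CPM. Genes without a count in the poly I:C group were Ttc39a (at least 17.3-fold lower), Lrrk2 (13.5), Pianp (10.3), Trim24 (8.02), Ccdc85b (7.68), Klhdc2 (6.95) and Pgf (5.85). Ppan stood at 1.35 against 100.1 CPM. Of 5273 genes 3428 were called, 1651 higher and 1777 lower, 1818 of them by at least 1.5. The median of all genes was -0.10, moving to -0.21 with DESeq2 size factors and to -0.88 with library totals, where 975 were higher and 3087 lower. Changes smaller than this, such as those of Irf8 (-0.34 ± 0.08) and Batf3 (-0.60 ± 0.21), thus depended in size on scaling. Under those scalings Irf8 stood at -0.45 and -1.12, Batf3 at -0.72 and -1.38 and Xcr1 at -0.50 and -1.16. Xcr1 was not called (-0.39 ± 0.18, adjusted p = 0.0544), but was with DESeq2 (adjusted p = 0.0247), with DESeq2 size factors (0.0118), with library totals (4.48e-09), with only the groups compared (0.0179) and without untreated library C (0.0395). Batf3 had adjusted p = 0.103 without untreated library C.

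With poly I:C all 31 interferon-stimulated genes rose (31 adjusted over the list alone, adjusted p = 3.32e-13), such as Oasl1 (7.30 ± 0.13) and Irf7 (6.51 ± 0.17). So did all 17 maturation genes (17 adjusted over the list alone, adjusted p = 2.73e-14), such as Cd40 (6.40 ± 0.17), Cd83 (5.48 ± 0.12) and Relb (5.13 ± 0.15). All 13 NF-kB targets rose (13 adjusted over the list alone, adjusted p = 2.73e-14), such as Traf1 (5.88 ± 0.14), Nfkbia (4.33 ± 0.11), Nfkb2 (3.99 ± 0.19) and Icam1 (3.78 ± 0.11). Of 16 class I genes 15 rose (15 adjusted over the list alone, adjusted p = 2.73e-14), such as H2-D1 (3.36 ± 0.09), H2-K1 (2.84 ± 0.11), B2m (2.59 ± 0.09) and Tapbp (2.22 ± 0.11). Of 16 effector genes 14 rose and 1 fell (14 and 1 adjusted over the list alone, adjusted p = 8.18e-14), with Ccl22 at 5.59 ± 0.11. Of 15 apoptosis genes 12 rose and 1 fell (13 and 1 adjusted over the list alone, adjusted p = 1.66e-12), such as Bcl2a1b (6.12 ± 0.20), Bcl2a1d (4.31 ± 0.19), Bcl2l1 (2.45 ± 0.18) and Mcl1 (2.31 ± 0.12). The cDC1 list had 14 of 20 lower, such as Naaa (-2.74 ± 0.13), Rab7b (-2.73 ± 0.20), Clec9a (-1.97 ± 0.48) and Id2 (-1.41 ± 0.10), and 1 higher, the endocytic receptor gene Ly75 (4.00 ± 0.23), 1 and 15 adjusted over the list alone (adjusted p = 1.69e-10). Of 9 cAMP targets 7 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 9.7e-10), such as Nr4a3 (6.00 ± 0.20), Rgs1 (5.35 ± 0.19), Atf3 (3.51 ± 0.27) and Crem (2.08 ± 0.39).

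Further lists passed with poly I:C but not with an estimated correlation. Of 12 class II genes 6 rose and 3 fell (6 and 3 adjusted over the list alone), with H2-Eb1 (1.44 ± 0.07), H2-Ab1 (1.05 ± 0.06), Cd74 (1.01 ± 0.06) and H2-Aa (0.91 ± 0.07), adjusted p = 8.37e-10 and adjusted p = 0.165 with an estimated correlation. Of 20 proliferation genes 17 fell and 1 rose (17 and 1 adjusted over the list alone), such as Rrm2 (-3.26 ± 0.27), Top2a (-2.73 ± 0.19), Ccna2 (-2.52 ± 0.32) and Birc5 (-2.26 ± 0.26), adjusted p = 8.88e-07 and adjusted p = 0.0821 with an estimated correlation. Of 12 stress genes 9 rose and 2 fell (9 and 2 adjusted over the list alone), such as the heat shock genes Hspa1b (7.54 ± 0.38), Hspa1a (7.08 ± 0.20) and Dnajb1 (2.92 ± 0.19), adjusted p = 1.69e-08 and adjusted p = 0.0857 with an estimated correlation. Of 12 cholesterol genes 8 rose, such as Hmgcs1 (2.13 ± 0.25) and Fdps (1.73 ± 0.24), and 1 fell, 8 and 1 adjusted over the list alone, adjusted p = 1.78e-06 and adjusted p = 0.218 with an estimated correlation. Of 7 prostaglandin genes 2 rose, among them Ptger4 (3.56 ± 0.33, 161 ± 15.2 against 13.4 ± 3.92 CPM), and 5 fell, such as Ptgs1 (-3.69 ± 0.29), Ptger3 (-3.57 ± 0.47) and Alox5ap (-1.98 ± 0.11), 2 and 5 adjusted over the list alone, adjusted p = 1.35e-05 and adjusted p = 0.247 with an estimated correlation. Of 8 TLR3 genes 6 rose, such as Traf6 (2.79 ± 0.39), Azi2 (2.56 ± 0.40), Rela (1.91 ± 0.18) and Tbk1 (1.56 ± 0.30), and 1 fell (6 and 1 adjusted over the list alone), adjusted p = 9.12e-06 and adjusted p = 0.267 with an estimated correlation.

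Of 12 glycolysis genes 4 rose with poly I:C, such as Pfkfb3 (3.39 ± 0.23) and Pfkp (2.15 ± 0.14), and 4 fell, such as Tpi1 (-1.04 ± 0.26), 4 and 4 adjusted over the list alone, adjusted p = 3.48e-06 and adjusted p = 0.534 with an estimated correlation, the median being -0.01 and the mean 0.30. Csf1r (-3.52 ± 0.29), Ccr2 (-2.90 ± 0.60) and Lyz2 (-1.11 ± 0.12) fell among 4 macrophage genes (4 adjusted over the list alone), adjusted p = 1.44e-09 and adjusted p = 0.0505 with an estimated correlation. Cd209a fell (-3.58 ± 0.49) and Cd7 did not pass (-1.54, adjusted p = 0.282) among cDC2 markers (1 adjusted over the list alone), list adjusted p = 0.000146 and adjusted p = 0.267 with an estimated correlation. No mitochondrial transcript was called (0 adjusted over the list alone, adjusted p = 0.507). Tlr3 stood at 32.4 ± 19.9 CPM untreated and 3.36 ± 4.30 CPM with poly I:C, and Ptger2 at 11.3 and 1.35 CPM.

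Did PGE2 change the response to poly I:C? Several cytokine and chemokine genes were lower when PGE2 preceded poly I:C, while Il12b and Ccr7 were not called. Ccl4, a chemokine gene, fell from 967 ± 210 to 171 ± 25.3 CPM (-2.52 ± 0.16, adjusted p = 2.76e-32, n = 4 each). Cxcl9 fell from 5278 ± 155 to 3186 ± 290 CPM (-0.74 ± 0.11, adjusted p = 1.07e-05) and Cxcl10 from 5338 ± 283 to 4156 ± 180 CPM (-0.38 ± 0.08, adjusted p = 0.00037). Il27 fell from 544 ± 117 to 234 ± 44.3 CPM (-1.24 ± 0.17), and the type III interferon genes Ifnl2 (-3.09 ± 0.41, 18.1 against 156 CPM) and Ifnl3 (-2.38 ± 0.41, 22.7 against 118 CPM) fell. Il12b (-0.14 ± 0.09, adjusted p = 0.387, 3553 ± 479 against 3867 ± 312 CPM) and Ccr7 (0.05 ± 0.08, adjusted p = 0.799) were not called.

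Among the largest increases with PGE2 before poly I:C were Klrd1 (3.78 ± 0.52), the Notch ligand gene Dll4 (3.21 ± 0.47, 117 against 11.4 CPM), Cd63 (2.91 ± 0.28, 252 ± 21.4 against 32.6 ± 4.45 CPM) and Capg (2.74 ± 0.38), while Tmem8 stood at 52.0 ± 15.0 against 2.25 CPM. Gins2 (-2.61 ± 0.58), Fuca2 (-2.60 ± 0.44) and Stfa2 (-2.34 ± 0.45) fell. Irf8 rose (0.34 ± 0.08, adjusted p = 0.00119, 3843 ± 382 against 3009 ± 419 CPM) and Xcr1 fell (-1.23 ± 0.23, adjusted p = 1.75e-05, 79.1 ± 16.2 against 184 ± 18.4 CPM). Batf3 (0.16, adjusted p = 0.782), Crem (0.06, adjusted p = 0.946), Clec9a (0.21, adjusted p = 0.901) and Ptger4 (0.01, adjusted p = 0.991) were not called. In all, 563 genes were called, 265 higher and 298 lower, 106 of them by at least 1.5. Chosen after its value was seen, Ifitm1 had the smallest adjusted p (1.64 ± 0.08, adjusted p = 4.75e-46, 8060 ± 132 against 2561 ± 126 CPM).

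On top of poly I:C, PGE2 lowered 7 of 16 effector genes and raised 1, Ccl22 (0.40 ± 0.08), 2 higher and 7 lower adjusted over the list alone (adjusted p = 0.000627). NF-kB targets had 7 of 13 higher (7 adjusted over the list alone, adjusted p = 9.37e-06), such as Il1b (1.83 ± 0.25), Bcl3 (1.19 ± 0.22), Tnfaip2 (1.00 ± 0.14) and Nfkbia (0.59 ± 0.08). Of 17 maturation genes 4 rose, such as Fscn1 (1.11 ± 0.11) and Cd83 (0.52 ± 0.08), and Cd40 (-0.48 ± 0.10) fell (7 and 1 adjusted over the list alone, adjusted p = 0.00013). Of 4 macrophage genes Lyz2 fell (-0.60 ± 0.14, 1 adjusted over the list alone), adjusted p = 0.00569 and adjusted p = 0.472 with an estimated correlation. Interferon-stimulated genes went both ways, 6 of 31 higher, such as Ifit3 (1.12 ± 0.12) and Gbp2 (0.91 ± 0.10), and 8 lower, such as Rsad2 (-0.99 ± 0.11) and Cmpk2 (-0.69 ± 0.11), 9 and 9 adjusted over the list alone (adjusted p = 0.797). So did the cDC1 list, 4 higher, such as Flt3 (1.74 ± 0.22) and Plet1 (1.09 ± 0.11), and 4 lower, such as Ppt1 (-1.87 ± 0.18), of 20 (5 and 6 adjusted over the list alone, adjusted p = 0.823).

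Other lists did not pass on top of poly I:C. Pde4b (1.06 ± 0.19) and Dusp1 (0.99 ± 0.27) rose and 2 fell, such as Atf3 (-1.09 ± 0.22), among 9 cAMP targets (3 and 2 adjusted over the list alone, adjusted p = 0.164). Among 16 class I genes 1 rose and 2 fell (2 and 2 adjusted over the list alone, adjusted p = 0.776). Ciita, the master regulator of class II genes (0.75 ± 0.14), and Ctss (0.47 ± 0.11) rose and H2-DMa (-0.44 ± 0.11) and H2-Ob (-0.87 ± 0.22) fell among 12 class II genes (3 and 2 adjusted over the list alone, adjusted p = 0.609), with a median of -0.06, a mean of 0.04 and a test pointing down. Pfkfb3 (0.66 ± 0.16) rose and 2 fell, such as Pkm (-0.48 ± 0.10), among 12 glycolysis genes (1 and 4 adjusted over the list alone, adjusted p = 0.186), with a median of -0.10, a mean of 0.13 and a test pointing down. Among 12 stress genes 2 rose, such as Hspa1b (0.60 ± 0.16), and 1 fell (3 and 1 adjusted over the list alone, adjusted p = 0.0898). Among 20 proliferation genes 2 fell (0 adjusted over the list alone, adjusted p = 0.0918), and 1 among 7 prostaglandin genes (1 adjusted over the list alone, adjusted p = 0.0918). No member was called, or called adjusted over the list alone, for TLR3 (adjusted p = 0.609), cholesterol (0.823, median -0.09, mean 0.04, test up), apoptosis (0.823), mitochondrial (0.168) and cDC2 genes (0.0918).

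**Figure D4:**
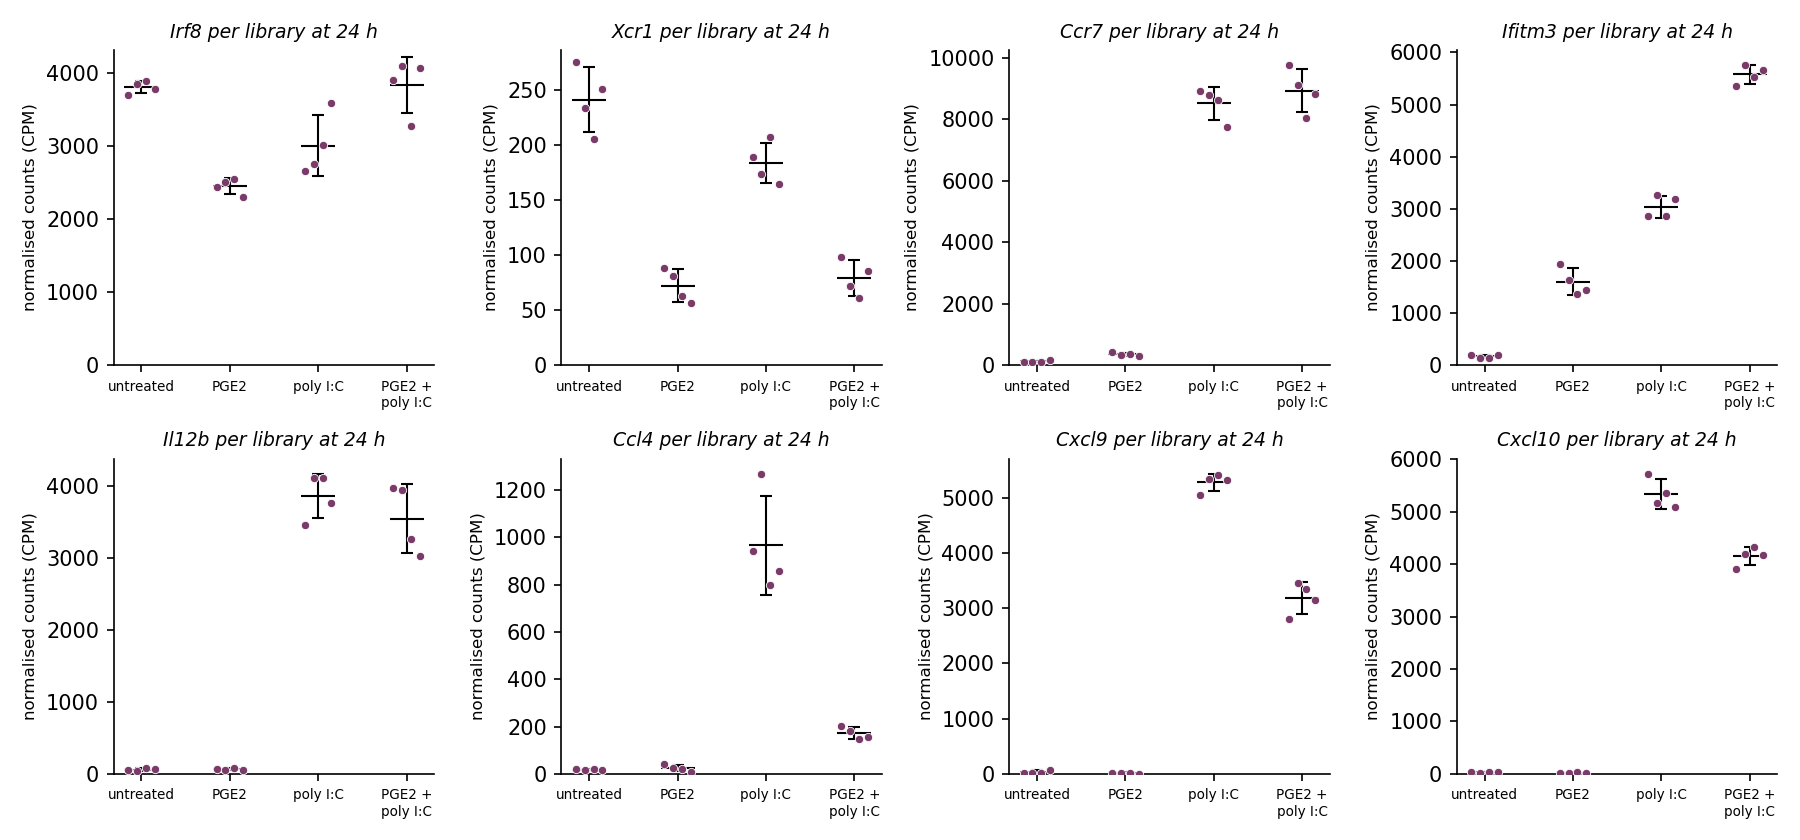
CPM per library (y axis) of Irf8, Xcr1, Ccr7, Ifitm3, Il12b, Ccl4, Cxcl9 and Cxcl10 in the 4 groups at 24 h (x axis), with points for libraries and lines for the mean ± SD of 4. Ccl4 averaged 967 CPM with poly I:C and 171 CPM with PGE2 before it, while Il12b averaged 3867 and 3553 CPM.

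Whether PGE2 acted differently with and without poly I:C was tested directly, and 173 of 5273 genes passed (45 higher, 128 lower, 49 by at least 1.5). Irf8 fell with PGE2 alone and rose with it on poly I:C, a difference of 0.93 ± 0.11 (adjusted p = 6.3e-11). Under poly I:C the effect of PGE2 differed by -1.60 ± 0.15 for Ccr7 (adjusted p = 7.62e-17), -3.04 ± 0.46 for Ccl4, -2.45 ± 0.14 for Ifitm3 and -2.62 ± 0.39 for Cacnb3. The sphingosine phosphate receptor gene S1pr2 (2.23 ± 0.56), Flt3 (1.37) and Naaa (0.72) differed in the other direction. Of 17 maturation genes 4 differed downward, such as Socs2 (-2.08), Fscn1 (-0.97) and Relb (-0.88), 6 adjusted over the list alone (adjusted p = 0.00223), and of 20 cDC1 genes 3 upward (4 adjusted over the list alone, adjusted p = 0.00223). For apoptosis genes 3 of 15 differed downward (5 adjusted over the list alone), adjusted p = 0.00428 and adjusted p = 0.13 with an estimated correlation. Without and with poly I:C, 97 genes were higher with PGE2 in both (12.6 expected, Fisher's exact p = 4.46e-66), 36 lower (9.61 expected, Fisher's exact p = 1.7e-12) and 9 opposite, with r = 0.27 across genes.

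The response to poly I:C in cells that had received PGE2 was broadly that of cells without it. Against PGE2 alone 3416 genes were called (1622 higher, 1794 lower, 1749 by at least 1.5, and 890 and 3085 with library totals), and the median of all genes was -0.11, or -0.20 with DESeq2 size factors and -0.88 with library totals. Cxcl10 (7.77 ± 0.16), Cxcl9 (7.46 ± 0.22) and Cmpk2 (7.83 ± 0.27) rose, and Dll4 was at least 47.9-fold higher. Ptgs1 fell (-5.21 ± 0.34), and Irf8 rose (0.59 ± 0.08, 3843 ± 382 against 2451 ± 107 CPM), but was at -0.19 with library totals. Across genes the poly I:C responses without and with PGE2 correlated at r = 0.92, with 1385 genes higher in both (508 expected), 1456 lower (605 expected) and 12 opposite.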

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

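The tests of explanations and the regroupings of libraries in this part were chosen after the results were seen, while the tests of the time difference and of PGE2 with and without poly I:C were fixed before.

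Library B of PGE2-deficient CM and library B of the EP3 antagonist stood apart, about midway between untreated and PGE2-treated cells. They scored 48.3% of the PGE2 response (others -2.90 to 3.95%) and 49.9% (others 97.0 to 99.5%). A swap of the pair is argued against, as PGE2-deficient CM B held a share of 0.466 (SE 0.013) of the EP3 antagonist profile. A swap needs the whole. Mixing between the pair needs equal shares from genes higher and lower with PGE2. In EP3 antagonist B these were 0.496 (SE 0.032) and 0.394 (SE 0.035), differing by 0.102, beyond 2 and within 3 SE. The SE come from resampled genes, not libraries, so neither limit decides. The limit was first 2 SE, which with the library nearest to PGE2-deficient CM B argued against mixing. It became the 3 SE of other tests after that was seen. That library was EP2 antagonist A (chi-square per degree of freedom 1.68, to 3 digits as with EP3 antagonist B, 2.54 to 2.73 within PGE2-deficient CM). The nearest of 35 libraries to EP3 antagonist B was PGE2-deficient CM B by chi-square (1.68 against 2.40 to 2.65 in its own group), but by correlation (0.9122) it ranked 2nd there and EP3 antagonist B ranked 9th for it, so that nearness does not settle mixing. Mixing and a partial response of these cultures cannot be told apart, as each may give a library between both profiles. The shares differed by -0.0312 in PGE2-deficient CM B and by -0.242 to -0.109 with the EP2 antagonist.

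The combined antagonists lowered the score far more than any single one, and their labels conflict. Had the EP1 and EP4 compounds been given and acted as the sum of their single effects, the fall would be 0.2681. The observed fall exceeded this by 1.73 (SE 0.066), which argues against it. The EP2 and EP4 falls sum to 1.026, exceeded by 0.974 (SE 0.079), so that either receptor alone may carry most of the score response. Tested by gene, only 5 departed from the sum. The EP1 and EP4 compounds acting beyond their sum stay open, since no group tests it.

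Scaled by library totals, most genes were lower with poly I:C than in untreated cells. The median was -0.827 from mean log2 values and -0.875 from the edgeR fit. A larger share of counts taken by the most abundant genes may account for some of this. The 500 most abundant took 54.0% of untreated and 68.7% of poly I:C counts. The median of -0.271 with these left out of the totals (-0.545 with 100) follows from such shares and is no separate test. Less messenger RNA per cell cannot be told apart from such a share. The median totals (309532 with poly I:C, 321384 untreated) depend on loading, and no cell numbers or added standards were used here.

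In 16 of 148 sets of 4 libraries, 1 library lay beyond the critical gap of Dixon's test at the 95% level, against 7.4 by chance. Library A of untreated cells at 4 h, the shallowest of its group, had a score of 10.8% (others -4.91 to -2.31%) and Ccr7 at 199 CPM (others at most 117). Clec9a stood at 67.6 CPM in PGE2-deficient CM A (20.2 to 27.4) and 68.1 CPM in EP2 antagonist C (14.5 to 23.0). EP1 antagonist A had 110698 counts in total (269235 to 296323), Xcr1 at 170 CPM (86.0 to 88.8) and Cxcl9 at 7.09 CPM (27.3 to 29.8), and EP1 antagonist D had Crem at 137 CPM (189 to 198). Xcr1 stood at 243 CPM in EP2 antagonist A (124 to 136), and Irf8 at 3520 CPM in EP3 antagonist B (2210 to 2370). EP4 antagonist A, the smallest library, had Cxcl9 at 201 CPM (4.76 to 18.5) and Cxcl10 at 146 CPM (18.5 to 19.0). Cxcl9 also stood at 55.7 CPM in library C of the combined antagonists (8.96 to 16.3) and at 76.8 CPM in untreated library D at 24 h (13.8 to 23.1).

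The effect of PGE2, as a log2 fold change, differed with poly I:C for 173 genes by the interaction test. Besides Irf8 (0.93), it was higher under poly I:C for Dll4 (5.73), Strbp (4.06), Ppfia1 (3.63), Mier2 (2.85), Hvcn1 (2.61), Ttyh3 (2.56), Mapk9 (2.54) and S1pr2 (2.23). It was lower for Ccr7 (-1.60), Wdr81 (-5.57), Sdc4 (-3.37), Adap2 (-3.17), Ccl4 (-3.04), Arid5a (-2.88), Cacnb3 (-2.62), Ifitm3 (-2.45) and Mmp25 (-2.41). The values of Dll4 and Wdr81, each without a count in 1 of the 4 groups, and of Strbp, Ppfia1, Sdc4 and Adap2, each with 1 to 3 counts in a group, depend on the prior count and are no exact differences. Leaving out single libraries ended the calls of Dll4 (14 of 16 removals, adjusted p up to 0.114), Adap2 (12, up to 0.126), Sdc4 (8, up to 0.202), Ttyh3 (7, up to 0.0895), Strbp (6, up to 0.34), Hvcn1 (4, up to 0.0956), Ppfia1 (2, up to 0.059), Mapk9 (1, 0.0604) and Mier2 (1, 0.0562).

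The effect of PGE2 differed between 24 and 4 h for 235 genes. Ccr7 (1.12), Tmem176b (3.64), Rac2 (3.12), Batf (3.07), Cacnb3 (2.76), Apol7c (2.51) and Cd300c2 (2.45) shifted up at 24 h. So did Batf3 (1.49), Hvcn1 (2.49) and Tab1 (2.45), which PGE2 lowered at 4 h. Crem (-3.92), Sdcbp2 (-7.71), Srxn1 (-3.25), Scin (-3.03), Aph1c (-3.03), Abcb8 (-3.02), Clec7a (-2.90) and Blvrb (-2.66) shifted down. The values of Sdcbp2 and Abcb8 (3 counts in untreated cells at 4 h) depend on the prior count. Leaving out single libraries ended the calls of Cacnb3 (12 of 16 removals, adjusted p up to 0.335), Apol7c (9, up to 0.16), Tab1 (9, up to 0.152), Abcb8 (8, up to 0.141), Clec7a (8, up to 0.13), Cd300c2 (6, up to 0.245) and Srxn1 (2, up to 0.125).

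To ask whether chance can be excluded, the 8 libraries of each pair of groups were regrouped 4 against 4 in all 35 ways and fitted alone. For PGE2 at 4 h the real grouping called 461 genes and the highest other 6, for control CM against PGE2-deficient CM 196 and 8, for PGE2-deficient and control CM against untreated cells 4 and 1 and 428 and 0. The EP2, EP3 and EP4 antagonists gave 82 and 10, 9 and 1, and 2 and 1, and the combination 579 and 0 against PGE2, 317 and 13 against EP4, 182 and 1 against EP2 and 75 and 1 against untreated cells. At 24 h the counts were 445 and 0 for PGE2, 2911 and 0 for poly I:C, 558 and 0 for PGE2 on top of poly I:C and 2899 and 0 for poly I:C on top of PGE2. In each of these 1 of 35 groupings, the real one, gave as many genes, which is the smallest share the design can give and was not adjusted over the comparisons. For the EP3 antagonist (9 genes), the EP4 antagonist (2 genes) and PGE2-deficient CM against untreated cells (4 genes) the counts from the fit of all 4 h groups fell to 0 without single libraries, so that these are not firm. For the EP1 antagonist all 35 gave 0, and chance cannot be excluded. For the interaction 4 of 100 draws gave at least the 173 genes (highest other 197) and for the time difference 3 of 100 gave at least the 235 (highest other 322). Redrawing labels also breaks up the PGE2 effect itself, so these shares cannot decide about chance.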

How the results depend on the processing

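The exclusions of a pair of libraries, either the shallow ones (EP4 antagonist A and untreated A at 4 h) or those that stood apart (PGE2-deficient CM B and EP3 antagonist B), and the score test of EP4 against EP2 were chosen after seeing the data.

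Counts of called genes for the main comparisons stayed within 1.5 times of their value under every alternative, with the exceptions given here. PGE2-deficient CM against untreated cells (5) gave 10 with no filter, 1 with DESeq2, 3 without the shallow pair and 0 without the pair apart. The EP2 antagonist (24) gave 82 with only the groups compared and 43 without the pair apart. The EP3 antagonist (4) gave 0 with no filter and 0 with DESeq2, 9 with only the groups compared and 1 without the pair apart. The EP4 antagonist (2) gave 0 with no filter, 0 with DESeq2 and 1 without the shallow pair. The combined antagonists against untreated cells (46) gave 29 with library totals, 75 with only the groups compared and 24 without the shallow pair. With no filter the interaction (173) gave 81 and the time difference (235) 129. The cause was not tested, except that no filter adjusts over more genes (19659 against 5754 at 4 h).

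Of the scores, EP1 against PGE2 reversed from 0.004 to -0.01483 with the 24 h signature, -0.01516 with genes changed by at least 1 and -0.1601 with the 4 h signature, which was formed from the same libraries and is biased. The biased signature gave -0.4691 for EP3 (adjusted p = 0.0286). EP4 against PGE2 was -0.06402 (adjusted p = 0.523) with the 24 h signature and kept -0.2722 in the replicate block with adjusted p = 0.0667. EP4 against untreated cells was 2.188 without the shallow pair (adjusted p = 0.117), where 3 against 3 libraries cannot pass. The combination against untreated cells was 0.1831 (adjusted p = 0.0727) with the 24 h signature and 0.541 (adjusted p = 0.0667) with genes changed by at least 1. The cause was not tested.

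Correlations across genes fell to 0.17 (PGE2 at 4 h with CM), 0.135 (4 h with 24 h) and 0.0925 (without and with poly I:C) with DESeq2 and to 0.111, 0.0997 and 0.0626 with no filter, settings that bring in genes with few counts. Shared lower genes fell to 24 and 18 with no filter for the last pairs. Lists called for PGE2, CM, poly I:C and PGE2 on poly I:C numbered 46 of 88, 27 with an estimated correlation. Of the genes the naming rule gives, 8490 values under alternatives kept their side of the threshold, 644 lost and 38 gained a call. With library totals Pkm under poly I:C (-0.02277) and Irf8 for poly I:C on PGE2 (-0.1875) reversed, as that scaling moved the median gene there to -0.875 and -0.881. Xcr1 with the combined antagonists was called in the block (adjusted p = 0.048). Called list members whose calls ended when single libraries were left out are mostly counted without being named, such as Ccl22, Psme1, Ldha and Slc16a3 for PGE2 at 4 h, Mcl1, Ccr2, Cd86 and Hspa5 for CM, H2-Aa, Bak1, Crtc2 and Csf1r for PGE2 at 24 h, and Nr4a3, Mcm6 and Plk1 for PGE2 on poly I:C. For CM, Crem, Ctla2a and Scin lost calls just with only the groups compared.

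Leaving out 1 library at a time gave these ranges of counts: PGE2 at 4 h 404 to 472, CM 141 to 306, PGE2-deficient CM 0 to 7, control CM against untreated cells 328 to 429, EP1 0 to 0, EP2 7 to 20, EP3 0 to 3, EP4 0 to 3, the combination against PGE2 402 to 487, EP4 205 to 284, EP2 72 to 121 and untreated cells 15 to 40. At 24 h they were PGE2 310 to 399, poly I:C 3379 to 3456, PGE2 on poly I:C 456 to 525, poly I:C on PGE2 3361 to 3450, the interaction 129 to 170 and the time difference 175 to 261. Libraries behind moves above 1.5-fold were PGE2-deficient CM A (141), untreated B (2) and D (0) and PGE2-deficient CM B (0), PGE2 A, B and C (9, 7, 15) and EP2 antagonist A, B and D (15, 13, 7), EP4 antagonist C (205), EP2 antagonist D (72) and combined A (78), and untreated A, B and C (22, 21, 15) and combined B, C and D (27, 22, 25). For EP3 they were PGE2 A and B (0, 1) and EP3 antagonist A, B, C and D (0, 1, 0, 1), and for EP4 PGE2 A, B and D (0, 0, 1) and EP4 antagonist A, B, C and D (1, 0, 0, 0).

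Score ranges were 2.406 to 2.539 for PGE2 and -0.02967 to 0.02977 for EP1 (reversed without PGE2 A, PGE2 D or EP1 antagonist A). They were -0.7937 to -0.7237 for EP2, -0.4491 to -0.04495 for EP3 (the last without EP3 antagonist B), -0.3057 to -0.2435 for EP4 and -2.036 to -1.961 for the combination. Against untreated cells they were 2.408 to 2.543 (EP1), 1.646 to 1.784 (EP2), 1.992 to 2.398 (EP3), 2.135 to 2.267 (EP4) and 0.4053 to 0.5341 (combination, adjusted p = 0.0667 without any of its libraries). They were -1.277 to -1.204 for the combination against EP2, -1.758 to -1.69 against EP4 and 0.452 to 0.5221 for EP4 against EP2.

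Residual correlations of the same replicate letter had a median of 0.0102 and a maximum of 0.0792 at 4 h, and 0.0152 and 0.0533 at 24 h, under the 0.1 set for treating letters as pairs. As 24 of 36 and 14 of 16 libraries correlated best with their own letter, a weak pairing was present. With the letter as a block, PGE2 at 4 h called 504 genes, CM 241 and PGE2 at 24 h 442. Depth limits the low genes, as a count of 0 allowed 10.2 CPM at the median total. Of simulated 2-fold changes 53.7% were called at 4 h.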
